A study of Mus musculus with 24 samples.

How the data were processed

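Total RNA from mouse liver was depleted of ribosomal RNA with a kit that its name gives as one for bacteria, and libraries were sequenced in paired-end mode, per the labels' protocols. The labels do not say whether the library kit marks strand, so reads of a gene and of its antisense partner cannot be told apart. The authors deposited raw counts per gene, whole numbers with a different total in each library. They also deposited TPM values, which are corrected for gene length and scaled to the same total in every library. The genome build mm39 and the tool DESeq2, without a version, are named in the submitters' processing notes. The aligner, the counter and the annotation release are not given in the sources used here.

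The 24 libraries were placed in 4 groups of 6 by their treatment labels. Replicate numbers follow the order of the labels and pair no samples. Of 49315 genes in the count table, 174 had no symbol and held 0.0111 to 0.0178% of the counts. They were not removed before the filter and the tests, but could not be named or belong to a gene list. All 60 pairs of replicates differed beyond sampling noise, with a chi-square per gene of 29.36 to 277.5. Total counts were 20976459 to 30288385 per library, so that a gene at 1 CPM after TMM scaling rests on 16.4 to 34.2 counts, and the edgeR biological coefficient of variation, the spread between libraries beyond counting error, was 0.272.

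Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group with a minimum count of 10, TMM factors, glmQLFit with robust estimation, glmQLFTest, 2-sided) in 1 model with a mean per group. The filter kept 17216 genes and 99.82 to 99.95% of the counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts with at least 2-fold change are given beside. The comparisons were tumour-bearing against control livers in each genotype, the difference of these effects, and genotype in control and in tumour-bearing livers. Gene lists, 46 in number and fixed in advance, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 43 lists with at least 4 tested members, and again with a correlation estimated per list and with fry. Shares of counts by gene class were compared by 2-sided exact permutation tests in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.

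Genes were named by a rule that was fixed, like the gene lists and the first group of alternatives, before the data were examined. It gives Abcb4, Akt1 and Yap1, the 8 genes with the largest rise and the 8 with the largest fall in each comparison (called, at least 5 CPM in the higher group, complete separation of the libraries except for the difference of effects, no predicted genes), and up to 4 called members of each list that passed camera or had the largest share of called members (at least 1 CPM), with the largest called member the other way. For a list with no call it adds the 2 members of highest CPM, which are not printed. Of the members of lists the text prints 1 or 2 examples and some of those that went the other way. That choice of examples was made after values were seen and partly after the alternatives had been run, so counts of kept calls are given for all genes the rule yields. Not every gene that the rule yields is reported here. Outside the rule, and chosen after their values were seen, are the Mdr2-/- tumour effects of Ankrd1, Ccl2, Col1a1, Mcm6 and Muc13, the wild-type tumour effects of Gpc3 and Muc13, and Abcb1b in controls.

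The alternatives were DESeq2 size factors, upper-quartile factors or total library size in place of TMM, no filter (34237 genes) or a stricter one (14530 genes), DESeq2 1.42.0, limma voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), only the 12 libraries compared, the range of the number in the sample titles (below 2000 or not) as a covariate, removal of mitochondrial and haemoglobin genes, and no robust estimation. Added after seeing the data were fits without each library, without 2 libraries that stood apart, and with the share of 7 nuclear non-coding RNAs as a covariate. On data simulated from the wild-type tumour comparison (16985 genes), edgeR made 6 false calls. In it edgeR recovered 79 of 100 genes changed 2-fold and 98 of 100 changed 4-fold. Camera called the changed list and 0 of 200 random lists, which cannot test lists of correlated genes. Gene order around Abcb4 came from a table of GRCm38.p6, not the assembly of the counts, so no coordinates are given.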

Results

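RNA sequencing counts were obtained from mouse liver tissue in 4 groups of 6 libraries each. Tumour-bearing livers came from mice in which AKT and YAP1 had been integrated into the genome by a transposon, a procedure that gives rise to cholangiocarcinoma, a cancer of the bile duct epithelium. Control livers had received an empty vector. Each condition was studied in wild-type mice and in Mdr2-/- mice, which lack Abcb4 (Mdr2), the canalicular phospholipid transporter whose loss leads to bile duct injury. The total count per library was 20976459 to 28416901 in wild-type controls and 23016702 to 30288385 in wild-type tumour-bearing livers. It was 26974376 to 30053571 in Mdr2-/- controls and 24245316 to 28304090 in Mdr2-/- tumour-bearing livers. Levels are CPM, counts per 1000000 counts after TMM scaling (mean ± SD, n = 6 per group). Changes are log2 fold changes (± SE) from a single edgeR quasi-likelihood model of all 24 libraries, in which 17216 genes were tested. The labels call the tissues individual without stating that each library came from a separate animal, so the p-values measure the spread between these samples.

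Abcb4 (ENSMUSG00000042476), the targeted gene, was measured first because it checks the genotype labels. Its level was 285 ± 49.8 CPM in wild-type controls and 233 ± 67.9 CPM in wild-type tumour-bearing livers, against 32.6 ± 6.81 CPM in Mdr2-/- controls and 31.0 ± 14.0 CPM in Mdr2-/- tumour-bearing livers. Every Mdr2-/- library lay below every wild-type library, the highest Mdr2-/- value being 59.3 CPM and the lowest wild-type value 165 CPM. The genotype difference was -3.13 ± 0.23 in controls (edgeR adjusted p = 2.43e-10) and -2.91 ± 0.23 in tumour-bearing livers (adjusted p = 1.46e-08). Between tumour-bearing and control livers, Abcb4 differed by -0.07 ± 0.21 in Mdr2-/- mice (edgeR adjusted p = 0.819) and by -0.29 ± 0.21 in wild type (adjusted p = 0.333).

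Akt1 (ENSMUSG00000001729), the mouse counterpart of one of the delivered oncogenes, was at 34.5 ± 9.36 CPM in wild-type controls and 98.2 ± 41.9 CPM in wild-type tumour-bearing livers, a rise of 1.51 ± 0.26 (edgeR adjusted p = 0.000103). In Mdr2-/- mice it rose from 55.1 ± 6.92 to 103 ± 34 CPM, by 0.90 ± 0.25 (adjusted p = 0.00958). Tumour-bearing livers ranged from 58.5 to 162 CPM in wild type and from 44.9 to 134 CPM in Mdr2-/-, where replicate 1 lay below all 6 controls. Yap1 (ENSMUSG00000053110) fell in tumour-bearing Mdr2-/- livers, from 73.3 ± 11.2 to 51.6 ± 6.65 CPM (-0.51 ± 0.15, edgeR adjusted p = 0.0137), a call that was lost on the authors' TPM (limma on log2(TPM + 1), adjusted p = 0.161). In wild type Yap1 differed by -0.12 ± 0.15 (adjusted p = 0.6). The labels do not give the species of the delivered sequences, and how far their reads are counted in the mouse genes is not known. Xist, the X-inactivation RNA, was at 533 CPM or more in every library. The highest value of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y in any library was 0.809 CPM.

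**Figure D1:**
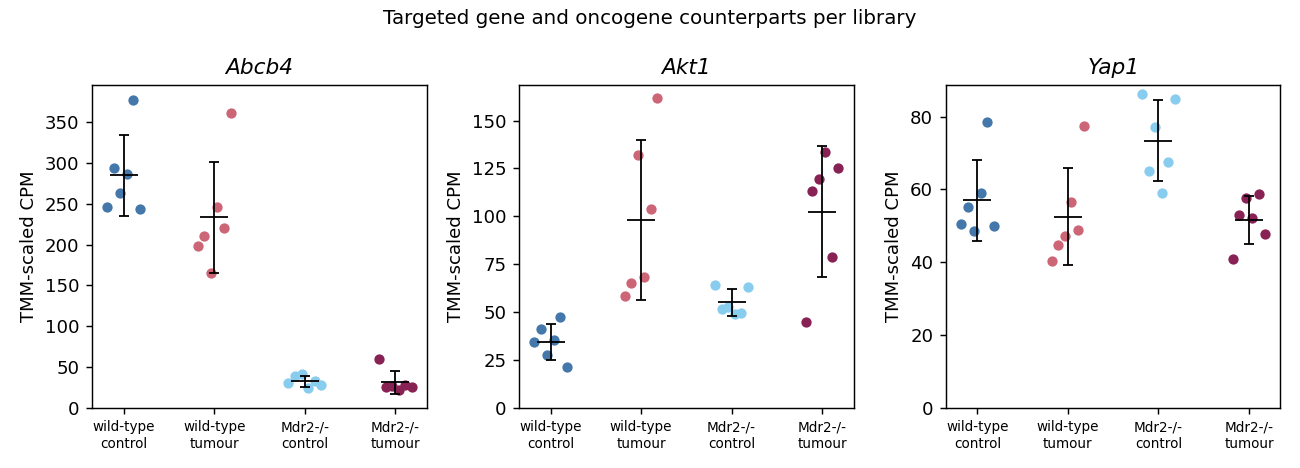
CPM, scaled by TMM, of Abcb4, Akt1 and Yap1 in each of the 24 libraries, with the 4 groups along the horizontal axis; dots are libraries, and the horizontal bar with whiskers gives the mean ± SD (n = 6). All 12 Mdr2-/- libraries lie at or below 59.3 CPM for Abcb4, and all 12 wild-type libraries at or above 165 CPM.

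The first 2 principal components of log2 CPM held 36.4% and 20.9% of the variance, and wild-type controls lay apart from the other 3 groups on the first. One library in each tumour-bearing group stood apart from its group. Wild-type replicate 6 had a second component of -40.58, among the Mdr2-/- controls, although its Abcb4 level of 361 CPM was the highest of its group. Mdr2-/- replicate 1 had a first component of -7.70, against -41.04 or less in the other 5. The model without these 2 libraries, an alternative chosen after seeing the data, called 6019 genes for the tumour effect in Mdr2-/- and 5222 in wild type. It called 2928 for the difference of these effects, 9347 for genotype in controls and 2702 for genotype in tumour-bearing livers.

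The composition of the libraries differed between groups. Mitochondrial-encoded genes took 7.57 ± 1.06% of the counts in wild-type controls and 4.34 ± 0.409% in Mdr2-/- controls (SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.0115 over 16 tests). The share was 5.45 ± 1.14% in wild-type tumour-bearing livers (n = 6, exact permutation p = 0.0152, adjusted p = 0.0303 against wild-type controls), a call lost as a share of the authors' summed TPM, where the difference was -3.45 (exact permutation, adjusted p = 0.0554) percentage points. In Mdr2-/- tumour-bearing livers it was 3.82 ± 1.03% (n = 6, exact permutation p = 0.286, adjusted p = 0.327 against Mdr2-/- controls). A group of 7 abundant nuclear non-coding RNAs was formed after seeing the data, from Malat1, Neat1, Xist, Rn7sk, Rpph1, Rmrp and Gm26917. It took 6.24 ± 1.44% of the counts in Mdr2-/- tumour-bearing livers and 3.19 ± 1.02% in Mdr2-/- controls (n = 6, exact permutation p = 0.00216, adjusted p = 0.0115), with no overlap between the groups. The same share was 5.44 ± 1.59% in wild-type tumour-bearing livers and 4.29 ± 0.959% in wild-type controls (n = 6, exact permutation p = 0.156, adjusted p = 0.192). The 10 most abundant genes took 20.9 ± 0.564% of the counts in wild-type controls, 19.1 ± 1.05% in wild-type tumour-bearing livers, 17.9 ± 0.387% in Mdr2-/- controls and 16.2 ± 1.21% in Mdr2-/- tumour-bearing livers. On the authors' summed TPM the tumour-bearing minus control difference in Mdr2-/- mice was 2.70 (exact permutation, adjusted p = 0.233) percentage points, the opposite direction, and 7.57 (exact permutation, adjusted p = 0.0519) for the non-coding RNAs.

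**Figure D2:**
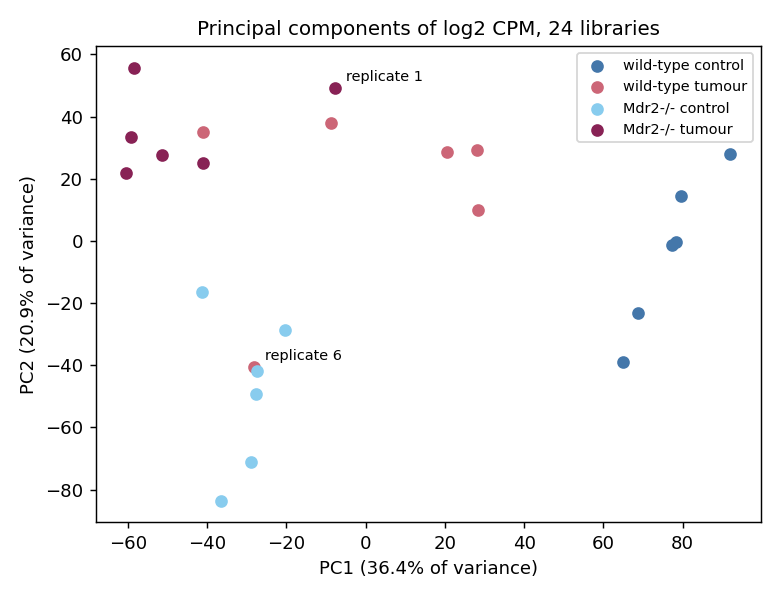
First and second principal component of log2 CPM over the tested genes, with the percent of variance on each axis; each dot is one of the 24 libraries, coloured by group, and the 2 libraries that stood apart from their groups are marked by their replicate number. Wild-type controls have first components of 64.92 to 91.99, and all other libraries 28.33 or less.

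The first comparison of the series asks what differs between tumour-bearing and control livers of Mdr2-/- mice. edgeR called rises for 13 of 22 bile duct markers and 6 of 11 oncofetal and hepatoblast genes and falls for 13 of 19 hepatocyte secreted proteins and lineage factors. None of these lists kept its camera call (adjusted p = 0.723 with an estimated correlation). Spp1, which encodes osteopontin and marks bile duct epithelium, rose from 109.8 ± 74.6 to 2174 ± 942 CPM (4.31 ± 0.54), and Gpc3, the oncofetal proteoglycan glypican 3, by 3.14 ± 0.44. Alb, which encodes albumin, fell by 1.09 on the log2 scale, and Hnf4a, a hepatocyte transcription factor, by 1.12.

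Of the cholangiocyte markers, 13 of 22 rose (14 adjusted over the list alone, camera adjusted p = 0.000677, adjusted p = 0.723 with an estimated correlation). Ehf (2.84 ± 0.61), an epithelial transcription factor, and Krt7 (2.54 ± 0.50), a keratin of bile ducts, were among them. Among oncofetal and hepatoblast genes, 6 of 11 rose (6 adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.723 with an estimated correlation). Igf2bp1, a fetal RNA-binding protein, rose by 7.02 ± 0.89. The fetal growth factor Igf2 (4.01 ± 1.07) and the fetal serum protein Afp (3.89 ± 0.87) rested on replicate 3 of the tumour-bearing livers, without which they were at 0.20, no longer called, and 0.84. Among hepatocyte secreted proteins and lineage factors, 13 of 19 fell (14 adjusted over the list alone, camera adjusted p = 1.38e-07, adjusted p = 0.723 with an estimated correlation). Asgr2, a subunit of the asialoglycoprotein receptor, changed by -1.20 ± 0.18. Of the genes of bile acid synthesis and transport, 9 of 20 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.723 with an estimated correlation). Abcb11, the canalicular bile salt export pump, changed by -1.02 ± 0.22 and Abcg5, a sterol exporter, by -0.90 ± 0.16, whereas Slco1a1, an importer of organic anions, rose (0.65 ± 0.21). Of cytochrome P450 drug-metabolising enzymes, 10 of 15 fell (10 adjusted over the list alone, camera adjusted p = 0.000677, adjusted p = 0.723 with an estimated correlation). Cyp2b10, which responds to the nuclear receptor CAR, changed by -2.11 ± 0.37, and Cyp1a2 changed by -1.24 ± 0.26. Of urea cycle and gluconeogenesis genes, 10 of 14 fell (11 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.723 with an estimated correlation), including Ass1 (-1.17 ± 0.20) and Tat (-1.12 ± 0.26).

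Of the NRF2 and glutathione genes, 9 of 16 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00144, adjusted p = 0.723 with an estimated correlation). Gsta1 changed by -1.51 ± 0.42, and Slc7a11, a cystine importer, by 0.82 ± 0.26. Among immediate early and heat shock genes, 5 of 15 fell (5 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.723 with an estimated correlation), led by Fosb (-1.80 ± 0.46) and Egr1 (-1.77 ± 0.47). Among Kupffer cell markers, 5 of 10 fell (5 adjusted over the list alone, camera adjusted p = 0.00409, adjusted p = 0.723 with an estimated correlation). Timd4, a surface receptor of resident liver macrophages, was at -1.0 ± 0.15, and Marco, a scavenger receptor, at -0.94 ± 0.34. The call of Marco was lost without Mdr2-/- tumour-bearing replicate 2 (-0.77) or 3 (-0.81) or 6 (-0.97) or Mdr2-/- control replicate 3 (-0.83) or 5 (-0.88). The call of Slco1a1 was lost without Mdr2-/- tumour-bearing replicate 1 (0.57) or 2 (0.55) or Mdr2-/- control replicate 1 (0.59) or 6 (0.56). Of the acute phase proteins, 7 of 17 fell (9 and 1 the other way adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.723 with an estimated correlation), among them Hp (-1.01 ± 0.17) and Lbp (-0.99 ± 0.16). Of sinusoidal endothelial markers, 5 of 10 fell (5 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.731 with an estimated correlation), with Dnase1l3 at -0.86 ± 0.16. Extracellular matrix genes did not pass as a list, although 8 of 24 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0562). For cell cycle genes, 8 of 26 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.363), and this list did not pass either.

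Across all genes tested, edgeR called 5995 (3074 up and 2921 down), of which 1580 rose and 338 fell by at least 2-fold. The 8 largest rises with complete separation of the libraries were Cdh16, Slco1a6, Sncg, Lrp2, Akr1cl, Efhd1, Wfdc18 and Prss35, at 4.53 to 6.93. The 8 largest falls, Cyp2b10, Ptgds, Hcar2, Egr1, Dnah1, Gpnmb, Myo7b and Adssl1, ranged from -2.11 to -1.68. With total library size in place of TMM the calls were 5565 up and 924 down, and with upper-quartile factors 4058 up and 1967 down. On the authors' TPM they were 4109 up and 1036 down with 1, and 3927 up and 953 down with 0.1, added before taking logs. These scalings shifted the median log2 fold change of all genes by 0.245, 0.119, 0.102 and 0.111, and the changes given here are relative to the TMM scaling. With the share of the 7 nuclear non-coding RNAs as a covariate, an alternative chosen after seeing the data, 960 genes were called (697 up and 263 down), 765 of them among the 5995. The fold changes of the 5995 came to a median 0.452 of their size, and 4986 kept their sign. For the 5230 no longer called the median was 0.369, with SEs a median 1.16 times as large. Of the 62 called results that the naming rule gives in this comparison, printed or not, 28 lost their call under it and 1 changed sign. Of the 43 printed ones, 17 lost theirs. In 8 of these, among them Hnf4a (-1.12 ± 0.25 before and -0.26 ± 0.23 after) and Cyp1a2 (-1.24 ± 0.26 before and -0.56 ± 0.28 after), the fold change shrank to 0.229 to 0.586 of its size. The other 9, among them Mcm6 (-1.16 ± 0.26 before and -1.09 ± 0.37 after) and Ankrd1 (2.28 ± 0.58 before and 2.33 ± 0.78 after), kept 0.691 to 1.34 of it and lost the call with SEs 1.24 to 1.48 times as large. Over all alternatives, 31 of these 62 kept their call and direction.

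The second comparison of the series sets tumour-bearing against control livers of wild-type mice. Called as risen were 16 of 22 bile duct markers, 24 of 26 cell cycle genes and 20 of 24 extracellular matrix genes, and as fallen 12 of 20 bile acid genes and 10 of 13 female-biased liver genes. Each of these lists lost its camera call (adjusted p = 0.173 to 0.18 with an estimated correlation). Spp1 rose from 71.2 ± 31.0 to 641 ± 529 CPM (3.17 ± 0.51) and Col1a1, which encodes a chain of type I collagen, from 7.43 ± 1.80 to 48.7 ± 35.1 CPM (2.72 ± 0.38). Cyp7b1, an enzyme of the alternative bile acid pathway, changed by -2.20 ± 0.24.

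Among the cholangiocyte markers, 16 of 22 rose (17 adjusted over the list alone, camera adjusted p = 9.45e-08, adjusted p = 0.18 with an estimated correlation). Wfdc2 (4.13 ± 0.32) and Cftr (3.70 ± 0.76), the chloride channel of bile duct cells, led them. The mean log2 CPM of the markers relative to all 24 libraries was -0.80 to -0.52 in tumour-bearing replicates 1, 2 and 4 and 0.52 to 0.94 in 3, 5 and 6, against -1.84 to -1.37 in controls. In the cell cycle and DNA replication list, 24 of 26 rose (24 adjusted over the list alone, camera adjusted p = 9.96e-12, adjusted p = 0.173 with an estimated correlation). Mcm6 (2.47 ± 0.29), a subunit of the replicative helicase, and Aurkb (2.12 ± 0.39), a mitotic kinase, rose most. Of extracellular matrix and fibrosis genes, 20 of 24 rose (20 and 1 the other way adjusted over the list alone, camera adjusted p = 1.6e-10, adjusted p = 0.173 with an estimated correlation). Timp1, an inhibitor of matrix proteases, was at 3.42 ± 0.50. Of TGF beta signalling genes, 7 of 12 rose (7 and 1 the other way adjusted over the list alone, camera adjusted p = 0.0239, adjusted p = 0.204 with an estimated correlation). For YAP/TAZ target genes, 11 of 21 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.312 with an estimated correlation). Tgfb2 (3.13 ± 0.45) and Ankrd1 (2.76 ± 0.64) rose most, and Nt5e (-1.29 ± 0.24) fell. Of senescence and secretory phenotype genes, 9 of 11 rose (9 adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.1 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, was at 2.68 ± 0.39.

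Of monocyte and macrophage markers, 9 of 17 rose (12 adjusted over the list alone, camera adjusted p = 8.9e-05, adjusted p = 0.18 with an estimated correlation), including Ms4a7 (2.50 ± 0.52) and Itgax (2.12 ± 0.32). Of chemokines and myeloid growth factors, 12 of 17 rose (16 adjusted over the list alone, camera adjusted p = 4.67e-06, adjusted p = 0.173 with an estimated correlation). Ccl20 (3.42 ± 0.78) and Ccl2 (2.96 ± 0.49), which attract dendritic cells and monocytes, rose most. Other immune lists that camera called up, with their called members in parentheses, were interferon-stimulated genes (13 of 20), MHC class I genes (5 of 12), MHC class II genes (4 of 8) and bacterial sensing genes (8 of 15, with 1 the other way). Adjusted over the list alone, these counts were 13 (with 1 the other way), 6, 7 and 8 (with 1 the other way). Their camera adjusted p-values were 9.5e-05 to 0.0185 (adjusted p = 0.173 to 0.468 with an estimated correlation). T and NK cell markers did not pass as a list (camera adjusted p = 0.873). Of NRF2 and glutathione genes, 9 of 16 rose (10 and 1 the other way adjusted over the list alone, camera adjusted p = 0.000788, adjusted p = 0.204 with an estimated correlation). Gsta1 (3.10 ± 0.56) and Gstm3 (2.96 ± 0.45), glutathione transferases, rose most. Of adipocyte markers, 4 of 5 rose (4 and 1 the other way adjusted over the list alone, camera adjusted p = 0.00341, adjusted p = 0.173 with an estimated correlation). Cidec, a lipid droplet protein, was at 3.65 ± 0.38.

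Of hepatocyte secreted proteins and lineage factors, 12 of 19 fell (14 adjusted over the list alone, camera adjusted p = 2.94e-07, adjusted p = 0.18 with an estimated correlation). Fga, a fibrinogen chain, was at -1.05 ± 0.19. For bile acid synthesis and transport, 12 of 20 fell (12 adjusted over the list alone, camera adjusted p = 3.29e-07, adjusted p = 0.173 with an estimated correlation), including Slc10a1, the sinusoidal bile acid importer (-1.41 ± 0.20). Of fatty acid oxidation genes and PPAR alpha targets, 13 of 18 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 7.5e-05, adjusted p = 0.258 with an estimated correlation). Cyp4a14 was at -2.53 ± 0.40, and Fgf21, a fasting hormone, at 1.77 ± 0.49. Of cytochrome P450 genes, 9 of 15 fell (9 adjusted over the list alone, camera adjusted p = 7.29e-06, adjusted p = 0.18 with an estimated correlation), with Cyp1a2 at -1.32 ± 0.26. Among urea cycle and gluconeogenesis genes, 8 of 14 fell (9 adjusted over the list alone, camera adjusted p = 9.73e-05, adjusted p = 0.204 with an estimated correlation). Cps1, which starts the urea cycle, was at -1.28 ± 0.23. Of pericentral Wnt targets, 5 of 12 fell (7 adjusted over the list alone, camera adjusted p = 5.29e-05, adjusted p = 0.199 with an estimated correlation), with Oat (-1.45 ± 0.24) and Lgr5 (-1.22 ± 0.22). Of the female-biased liver genes, 10 of 13 fell (10 adjusted over the list alone, camera adjusted p = 4.62e-07, adjusted p = 0.173 with an estimated correlation). A1bg was at -3.42 ± 0.53. Of the mitochondrial-encoded messenger RNAs, 9 of 13 fell (11 adjusted over the list alone, camera adjusted p = 4.81e-06, adjusted p = 0.204 with an estimated correlation).

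In all, edgeR called 4891 genes in wild type (2915 up and 1976 down), 1479 of them up and 428 down by at least 2-fold. The 8 largest rises were Ang5, Cyp4a12a, Sdcbp2, Pla2g5, Spink1, Prss35, Fam83a and Ang4, at 5.04 to 6.70. The 8 largest falls were Cyp2c69, Cyp2c40, Hsd3b1, A1bg, Sult3a2, Ces3b, Cyp4a14 and Sult3a1, at -5.11 to -2.45. The Ang, Cyp2, Cyp3a, Cyp4a, Gsta, Gstm, Mup, Sult and Trav genes named in any comparison belong to families of near-identical genes, so that their single values are uncertain. With total library size alone the calls were 5783 up and 603 down, and on the authors' TPM 4498 up and 478 down with 1 and 5071 up and 498 down with 0.1 added, with medians of all genes shifted by 0.298, 0.255 and 0.288. The numbers in the sample titles were 2000 or above in all 6 tumour-bearing and 1 of 6 control wild-type libraries. With that range as a covariate, which is estimated mostly from the other groups, 3485 genes were called, and no range holds enough libraries of both wild-type groups for a comparison within it. Of the 106 called results that the naming rule gives here, 90 kept their call and direction under every alternative.

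**Figure D3:**
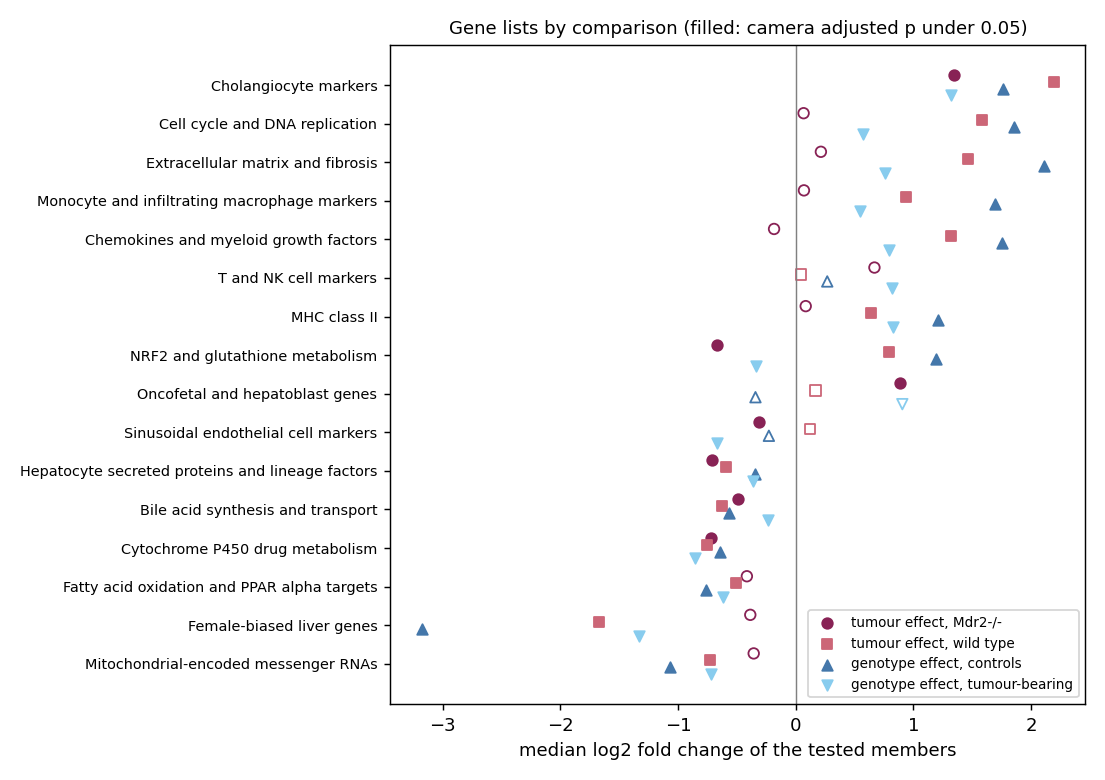
Median log2 fold change of the tested members of 16 gene lists (horizontal axis) in 4 comparisons, where circles and squares are the tumour effects in Mdr2-/- and wild-type mice and upward and downward triangles the genotype effects in control and tumour-bearing livers; filled symbols passed camera with its preset correlation, and no list passed with an estimated one. The cholangiocyte median is 1.34 and 2.19 for the tumour effects and the cell cycle median 0.07 and 1.58, while on log2(TPM + 1) the genotype medians of the hepatocyte list in controls (0.125) and of the bile acid list in tumour-bearing livers (0.035) are positive, where the medians of all genes move by 0.409 and 0.247.

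The interaction term tests whether the tumour effect differs between genotypes, and its log2 values are the Mdr2-/- effect minus the wild-type effect. A lower tumour effect in Mdr2-/- mice was called for 18 of 26 cell cycle genes, 12 of 24 extracellular matrix genes, 11 of 17 monocyte and macrophage markers and 11 of 16 NRF2 and glutathione genes. The camera calls of these lists did not hold (adjusted p = 0.354 to 0.487 with an estimated correlation). The tumour effect on Mcm6 was -1.16 ± 0.26 in Mdr2-/- and 2.47 ± 0.29 in wild type (difference -3.62 ± 0.39). For Col1a1 it was -0.15 ± 0.34 in Mdr2-/- and 2.72 ± 0.38 in wild type (difference -2.87 ± 0.50), and for Ccl2, a monocyte chemokine, -0.54 ± 0.41 in Mdr2-/- and 2.96 ± 0.49 in wild type (difference -3.50 ± 0.65). The Mdr2-/- tumour effects of these 3 genes were looked up after the differences were seen. The control livers these effects start from also differed. Mcm6 was at 2.75 ± 1.36 CPM in wild-type and 29.9 ± 9.38 CPM in Mdr2-/- controls, and at 15.0 ± 5.47 and 13.4 ± 2.88 CPM in the tumour-bearing livers.

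Of the cell cycle genes, 18 of 26 had a lower effect (19 adjusted over the list alone, camera adjusted p = 1.57e-09, adjusted p = 0.438 with an estimated correlation). In the extracellular matrix list, 12 of 24 had a lower effect (14 adjusted over the list alone, camera adjusted p = 0.000162, adjusted p = 0.487 with an estimated correlation), with Timp1 at -2.47 ± 0.63. Of the monocyte and macrophage markers, 11 of 17 had a lower effect (11 and 1 the other way adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.487 with an estimated correlation). The difference was -2.22 ± 0.57 for Gpnmb, a glycoprotein of macrophages, and -2.10 ± 0.43 for Itgax, an integrin of myeloid cells. Among chemokines and myeloid growth factors, 8 of 17 had a lower effect (9 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.487 with an estimated correlation), with Ccl7 at -3.66 ± 0.69. In the NRF2 and glutathione list, 11 of 16 had a lower effect (12 adjusted over the list alone, camera adjusted p = 9.59e-07, adjusted p = 0.354 with an estimated correlation). The tumour effect on Gsta1 was -1.51 ± 0.42 in Mdr2-/- and 3.10 ± 0.56 in wild type. Of the senescence and secretory phenotype genes, 4 of 11 had a lower effect (5 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.354 with an estimated correlation). Mmp12 (-3.81 ± 0.44) and Mmp13 (-3.06 ± 0.45), both matrix proteases, differed most. Other lists whose effect camera called lower were MHC class I genes (4 of 12), Kupffer cell markers (5 of 10), sinusoidal endothelial markers (4 of 10), glycolysis genes (5 of 16) and bacterial sensing genes (7 of 15). The counts were 5, 5, 5, 7 and 8 adjusted over the list alone, and camera adjusted p-values lay at 0.00412 to 0.0321 (adjusted p = 0.354 to 0.571 with an estimated correlation). Among female-biased liver genes, 6 of 13 had a higher effect and 1 had a lower effect (6 and 1 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.519 with an estimated correlation), led by Cyp3a44 at 6.46 ± 1.02, with Cyp2b13 the other way at -1.61 ± 0.60. The call of Cyp2b13 was lost in 18 of the 24 fits that each left out 1 library, over which it ranged from -2.17 to -1.43. Of the abundant non-coding RNAs of rRNA-depletion libraries, 4 of 7 had a higher effect (4 adjusted over the list alone, camera adjusted p = 0.00577, adjusted p = 0.519 with an estimated correlation), with Malat1 (1.64 ± 0.34) and Neat1 (1.5 ± 0.35). Among the cholangiocyte markers, 5 of 22 had a lower effect (5 adjusted over the list alone, camera adjusted p = 0.181), and the list did not pass.

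The interaction called 4355 genes (2042 higher and 2313 lower in effect in Mdr2-/-), 1415 and 1187 of them by at least 2-fold. The 8 highest were Cyp3a44, Cyp3a16, Cyp3a41b, Cyp3a41a, Mup16, Mup9, Cyp2c69 and Mup7, at 4.75 to 6.46. The 8 lowest were Tinag, Ang5, Sprr1a, Slpi, Cyp4a12a, Smpd3, Trav4-1 and Gstm3, at -4.84 to -4.14. Of the genes with a lower effect in Mdr2-/-, 1859 were higher in Mdr2-/- than in wild-type controls and not called between the tumour-bearing groups, and of those with a higher effect 1694 were lower and likewise not called. With upper-quartile factors the split was 2418 up and 1784 down (median shift 0.102), and on log2(TPM + 0.1) it was 1314 up and 2349 down (median shift -0.175). With the non-coding RNA share as a covariate, 2682 genes were called. Of the 65 called results that the naming rule gives here, 48 kept their call and direction under every alternative. Of the 78 printed genes with a called difference, those that lost the call under another setting were A1bg, Afp, Aqp1, Asgr2, Aurkb, Ccl20, Cdh16, Cidec, Cx3cr1, Cyp2b13, Cyp4a14, Dnase1l3, Efhd1, Fabp1, Fam83a, Fosb, Gpnmb, Hnf4a, Ms4a7 and Timp1.

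The tumour effects shared genes as well. In both genotypes 928 genes rose and 483 fell, where independent lists of the same lengths would share 520 and 335, and 478 genes were called in opposite directions. Of these, 235 rose and 243 fell in Mdr2-/-, where independent lists would share 353 and 495. With at least 2-fold changes in both, 507 genes rose and 33 fell in both (independent lists would share 136 and 8), and 102 went opposite ways, 65 of them up and 37 down in Mdr2-/- (39 and 29 for independent lists). Prss35, a serine protease, rose in both (4.53 ± 0.74 in Mdr2-/- and 5.46 ± 0.89 in wild type), as did 3 genes chosen after their values were seen, namely Ankrd1, a YAP target (2.28 ± 0.58 and 2.76 ± 0.64, the first no longer called with the non-coding RNA covariate), Muc13, an epithelial mucin (4.05 ± 0.58 and 3.76 ± 0.63), and Gpc3 (3.14 ± 0.44 and 3.36 ± 0.45). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.296 and a Spearman rho of 0.115. The comparisons share no library.

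Control livers of Mdr2-/- and wild-type mice were compared to find what differs between the genotypes without tumours. Higher in Mdr2-/- controls were 22 of 24 extracellular matrix genes, 26 of 26 cell cycle genes and 19 of 22 bile duct markers, and lower were 12 of 13 female-biased liver genes and 13 of 18 fatty acid oxidation genes. No camera call of these lists held (adjusted p = 0.16 to 0.213 with an estimated correlation). Col1a1 was at 87.2 ± 39.0 CPM in Mdr2-/- and 7.43 ± 1.80 CPM in wild-type controls (3.56 ± 0.39), and Cftr was at 3.34 ± 0.76. Sult3a1, a sulfotransferase of the female-biased set, was at 33.9 ± 11.2 against 3077 ± 894 CPM (-6.51 ± 0.62).

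In the extracellular matrix and fibrosis list, 22 of 24 were higher (22 adjusted over the list alone, camera adjusted p = 9.95e-11, adjusted p = 0.16 with an estimated correlation), with Timp1 at 3.33 ± 0.49. Of the hepatic stellate cell and myofibroblast markers, 7 of 15 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.16 with an estimated correlation), with Cygb (2.56 ± 0.20) and Pdgfrb (2.06 ± 0.23). Rgs5, a pericyte regulator of G protein signalling, was lower (-0.46 ± 0.19). The call of Rgs5 was lost in 17 of the 24 fits that each left out 1 library, over which it ranged from -0.56 to -0.36. Among TGF beta signalling genes, 7 of 12 were higher (7 adjusted over the list alone, camera adjusted p = 0.00352, adjusted p = 0.16 with an estimated correlation), with Itgb6, an epithelial integrin chain, at 3.41 ± 0.47. In the cell cycle list, 26 of 26 were higher (26 adjusted over the list alone, camera adjusted p = 5.68e-12, adjusted p = 0.16 with an estimated correlation), with Mcm6 (3.46 ± 0.29) and Mcm5 (2.82 ± 0.25). Of cholangiocyte markers, 19 of 22 were higher (20 adjusted over the list alone, camera adjusted p = 1.19e-06, adjusted p = 0.213 with an estimated correlation). Cldn4, a tight junction protein, was at 4.82 ± 0.54. Among YAP/TAZ target genes, 12 of 21 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.508 with an estimated correlation), with Tgfb2 (2.28 ± 0.44) and Myof (1.95 ± 0.25). Nt5e was lower (-1.81 ± 0.24). Among NRF2 and glutathione genes, 12 of 16 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.000324, adjusted p = 0.213 with an estimated correlation), with Gsta1 (4.28 ± 0.55) and Gstm3 (3.6 ± 0.46). Gclm, a subunit of the enzyme that starts glutathione synthesis, was lower (-0.71 ± 0.16). Among senescence and secretory phenotype genes, 9 of 11 were higher (9 adjusted over the list alone, camera adjusted p = 0.000157, adjusted p = 0.129 with an estimated correlation), with Mmp12 (4.08 ± 0.34) and Mmp13 (3.56 ± 0.35).

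Among monocyte and macrophage markers, 14 of 17 were higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 8.61e-07, adjusted p = 0.16 with an estimated correlation), with Ms4a7 (3.82 ± 0.52) and Cx3cr1 (3.31 ± 0.31). Mrc1, the mannose receptor, was lower (-1.06 ± 0.18). Of the chemokines and myeloid growth factors, 14 of 17 were higher (14 adjusted over the list alone, camera adjusted p = 8.61e-07, adjusted p = 0.16 with an estimated correlation). Ccl2 was at 4.13 ± 0.50. Of MHC class I genes, 12 of 12 were higher (12 adjusted over the list alone, camera adjusted p = 8.48e-06, adjusted p = 0.16 with an estimated correlation). Psmb8, an immunoproteasome subunit, was at 1.17 ± 0.16. Of MHC class II genes, 8 of 8 were higher (8 adjusted over the list alone, camera adjusted p = 0.000116, adjusted p = 0.213 with an estimated correlation), and Cd74, the invariant chain, was at 1.58 ± 0.25. Camera also called higher interferon-stimulated genes (13 of 20, with 1 the other way), dendritic cell markers (6 of 11, with 1 the other way), bacterial sensing genes (12 of 15, with 1 the other way), immediate early and heat shock genes (8 of 15) and glycolysis genes (9 of 16). Adjusted over the list alone, these counts were 14 (with 1 the other way), 6 (with 1 the other way), 12 (with 2 the other way), 9 and 9. Their camera adjusted p-values were 0.000157 to 0.0458 (adjusted p = 0.129 to 0.508 with an estimated correlation). Of T and NK cell markers, 6 of 16 were higher (5 adjusted over the list alone, camera adjusted p = 0.52), of B and plasma cell markers, 2 of 13 were higher and 1 lower (2 and 0 adjusted over the list alone, camera adjusted p = 1), and of immune checkpoint and regulatory T cell genes, 4 of 11 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.254).

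Among female-biased liver genes, 12 of 13 were lower (12 adjusted over the list alone, camera adjusted p = 2.68e-07, adjusted p = 0.16 with an estimated correlation). Cyp3a44 was at -6.60 ± 0.84. Among fatty acid oxidation genes and PPAR alpha targets, 13 of 18 were lower (13 adjusted over the list alone, camera adjusted p = 2.85e-06, adjusted p = 0.213 with an estimated correlation), with Cyp4a14 (-4.54 ± 0.44) and Acot1 (-2.94 ± 0.27), a fatty acyl thioesterase. In the bile acid list, 12 of 20 were lower (12 adjusted over the list alone, camera adjusted p = 0.000433, adjusted p = 0.213 with an estimated correlation), with Cyp7b1 at -2.45 ± 0.24 and Cyp8b1 at -1.63 ± 0.41. Each of the 13 mitochondrial-encoded messenger RNAs was lower (13 adjusted over the list alone, camera adjusted p = 3.63e-07, adjusted p = 0.194 with an estimated correlation). Of the hepatocyte secreted proteins and lineage factors, 9 of 19 were lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.508 with an estimated correlation), with a median of -0.348. On log2(TPM + 1) and log2(TPM + 0.1), where the median of all genes moved by 0.409 and 0.449, it was 0.125 and 0.125. Camera also called lower cytochrome P450 genes (7 of 15), abundant non-coding RNAs of rRNA-depletion libraries (6 of 7) and erythroid markers (2 of 9). The counts were 7, 6 and 2 adjusted over the list alone, and camera adjusted p-values lay at 0.000263 to 0.0395 (adjusted p = 0.23 to 0.488 with an estimated correlation).

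In control livers edgeR called 8690 genes (4512 higher and 4178 lower in Mdr2-/-), 1930 and 1992 of them by at least 2-fold. The 8 furthest higher were Sprr1a, Slpi, Ubd, Cib3, Tinag, Trav4-1, Smpd3 and Myo7b, at 4.72 to 5.30. The 8 furthest lower were Mup9, Mup16, Mup18, Sult3a2, Cyp3a44, Cyp2c69, Sult3a1 and Mup19, at -7.15 to -6.35. With total library size alone the split was 7247 up and 2325 down, and on the authors' TPM 8121 up and 1589 down with 1 and 8403 up and 1668 down with 0.1 added (median shifts 0.301, 0.409 and 0.449). Of the 123 called results that the naming rule gives here, 111 kept their call and direction under every alternative. Among printed genes, the calls of Cyp8b1, Gclm and Rgs5 were lost under another setting.

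The last comparison sets tumour-bearing Mdr2-/- livers against tumour-bearing wild-type livers. Genes higher in Mdr2-/- included 13 of 22 bile duct markers (with 1 the other way), 8 of 16 T and NK cell markers and 7 of 8 MHC class II genes, and genes lower there 10 of 10 sinusoidal endothelial markers and 9 of 15 cytochrome P450 genes. As lists they lost their camera calls (adjusted p = 0.138 with an estimated correlation). Abcb1b, a drug efflux transporter of the family of Abcb4, was at 32.1 ± 10.4 CPM in Mdr2-/- and 1.59 ± 0.463 CPM in wild type (4.33 ± 0.29), and in controls, looked up after this value was seen, the difference was 4.27 ± 0.29. Cd8a, the co-receptor of cytotoxic T cells, was at 3.04 ± 0.53, and Epcam, an epithelial adhesion molecule, at 2.37 ± 0.41.

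Among cholangiocyte markers in tumour-bearing livers, 13 of 22 were higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 8.99e-10, adjusted p = 0.138 with an estimated correlation), with Cldn7, a tight junction protein, at 2.22 ± 0.37. Their mean log2 CPM relative to all libraries was 0.65 to 1.73 in Mdr2-/- livers and -0.80 to 0.94 in wild-type livers, in 2 sets of 3 with none between -0.52 and 0.52. Aqp1, a water channel also of endothelium, was lower (-0.43 ± 0.11). Among extracellular matrix genes, 12 of 24 were higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 2.84e-10, adjusted p = 0.138 with an estimated correlation). Mmp7, a matrix protease, was at 2.25 ± 0.60. Loxl1, which crosslinks elastin, was at 1.75 ± 0.34, and Postn, a matrix protein of activated fibroblasts, was lower (-0.74 ± 0.22). The call of Postn was lost without Mdr2-/- tumour-bearing replicate 2 (-0.72) or 3 (-0.71) or 5 (-0.69) or 6 (-0.72) or wild-type tumour-bearing replicate 3 (-0.58) or 5 (-0.67). Further lists that camera called higher in Mdr2-/- were stellate cell and myofibroblast markers (5 of 15, with 1 the other way), TGF beta signalling genes (5 of 12), YAP/TAZ target genes (6 of 21, with 1 the other way) and Notch pathway genes (1 of 12). Adjusted over the list alone, these counts were 6 (with 2 the other way), 5, 10 (with 2 the other way) and 4. Their camera adjusted p-values were 0.0046 to 0.00817 (adjusted p = 0.138 to 0.306 with an estimated correlation). Of the cell cycle genes, 1 was higher and 1 lower of 26 (1 and 1 adjusted over the list alone). Camera called this list higher (camera adjusted p = 0.02, adjusted p = 0.54 with an estimated correlation) and fry did not (adjusted p = 0.174). Of T and NK cell markers, 8 of 16 were higher (9 adjusted over the list alone, camera adjusted p = 6.23e-05, adjusted p = 0.138 with an estimated correlation), with Cd8b1 at 2.16 ± 0.49. In the MHC class II list, 7 of 8 were higher (8 adjusted over the list alone, camera adjusted p = 1.63e-06, adjusted p = 0.138 with an estimated correlation), with H2-DMb1 (1.04 ± 0.21). Among the monocyte and macrophage markers, 5 of 17 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 1.62e-05, adjusted p = 0.138 with an estimated correlation), with Ms4a7 (1.82 ± 0.43) and Cx3cr1 (1.73 ± 0.28). Mrc1 was lower (-0.63 ± 0.18). The call of Mrc1 was lost without Mdr2-/- tumour-bearing replicate 3 (-0.57) or 6 (-0.57) or wild-type tumour-bearing replicate 1 (-0.54) or 2 (-0.60). The remaining immune lists that camera called higher were chemokines and myeloid growth factors (3 of 17), bacterial sensing genes (4 of 15), interferon-stimulated genes (3 of 20), MHC class I genes (4 of 12) and neutrophil markers (1 of 10). The counts were 9, 7, 3, 4 and 1 adjusted over the list alone, and camera adjusted p-values lay at 3.93e-05 to 0.0441 (adjusted p = 0.138 to 0.362 with an estimated correlation).

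All 10 sinusoidal endothelial markers were lower in tumour-bearing Mdr2-/- livers (10 adjusted over the list alone, camera adjusted p = 9.94e-11, adjusted p = 0.138 with an estimated correlation), with F8 (-1.05 ± 0.20) and Dnase1l3 (-0.91 ± 0.16). In the Kupffer cell list, 4 of 10 were lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.000232, adjusted p = 0.158 with an estimated correlation). Cd163, a haemoglobin scavenger receptor, was at -2.06 ± 0.35, and C6, a complement component, at 1.42 ± 0.25. In the fatty acid oxidation list, 10 of 18 were lower (15 adjusted over the list alone, camera adjusted p = 9.94e-11, adjusted p = 0.138 with an estimated correlation). Cyp4a14 was at -2.59 ± 0.40 and Fabp1, the liver fatty acid binding protein, at -1.12 ± 0.21. In the cytochrome P450 list, 9 of 15 were lower (10 adjusted over the list alone, camera adjusted p = 1.18e-09, adjusted p = 0.138 with an estimated correlation), with Cyp2c37 (-2.38 ± 0.25) and Cyp2b10 (-2.21 ± 0.37). In the female-biased list, 7 of 13 were lower (8 adjusted over the list alone, camera adjusted p = 1.62e-05, adjusted p = 0.158 with an estimated correlation), with Sult3a1 (-3.32 ± 0.54) and Cyp2b13 (-2.99 ± 0.45). Among mitochondrial-encoded messenger RNAs, 10 of 13 were lower (13 adjusted over the list alone, camera adjusted p = 1.15e-09, adjusted p = 0.138 with an estimated correlation). Other lists that camera called lower were hepatocyte secreted proteins and lineage factors (6 of 19), NRF2 and glutathione genes (3 of 16), lipogenesis genes (2 of 17, with 1 the other way) and adipocyte markers (3 of 5). Adjusted over the list alone, these counts were 7, 3 (with 1 the other way), 5 (with 1 the other way) and 3. Their camera adjusted p-values were 5.24e-07 to 0.00817 (adjusted p = 0.138 to 0.306 with an estimated correlation). Among bile acid genes, 2 of 20 were lower (6 adjusted over the list alone, camera adjusted p = 0.00256, adjusted p = 0.28 with an estimated correlation), with a median of -0.239. On log2(TPM + 1) and log2(TPM + 0.1), where the median of all genes moved by 0.247 and 0.27, it was 0.035 and 0.035. The urea cycle list had a median of -0.264 (camera adjusted p = 0.0294, adjusted p = 0.459 with an estimated correlation, fry adjusted p = 0.188), and the skeletal muscle list one of -0.52 (camera adjusted p = 0.0294, adjusted p = 0.558 with an estimated correlation, fry adjusted p = 0.314).

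In total 1917 genes were called between tumour-bearing livers (1228 higher and 689 lower in Mdr2-/-), 672 and 218 by at least 2-fold. The 8 furthest higher were Abcb1b, Wfdc18, Scara5, Tmem45a, Lrrn1, Cib3, Itgbl1 and Fxyd3, at 2.66 to 4.33. The 8 furthest lower were Sult2a5, Cyp2b13, Abcb4, Cyp4a14, Colec10, Cyp2c37, Cyp2b10 and Ppp1r3g, at -3.56 to -2.17. The call of Ppp1r3g was lost without Mdr2-/- tumour-bearing replicate 6 (-2.16) or wild-type tumour-bearing replicate 4 (-1.93). With total library size alone 2927 genes were called (2668 up and 259 down, median shift 0.246), and by limma voom with quality weights 4120. On the authors' TPM the calls were 3053 up and 253 down with 1 and 2834 up and 235 down with 0.1 added (median shifts 0.247 and 0.27). Leaving out Mdr2-/- tumour-bearing replicate 6 gave 1116 calls, wild-type tumour-bearing replicate 2 gave 1232 and wild-type tumour-bearing replicate 4 gave 1184. Of the 104 called results that the naming rule gives here, 74 kept their call and direction under every alternative. Printed genes whose call was lost under another setting were Aqp1, Mmp7, Mrc1, Postn and Ppp1r3g.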

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

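The tests of other splits of the libraries, of the non-coding RNA covariate and of the 3 explanations for the female-biased genes were chosen after the results were seen. The title-number covariate was chosen in advance, and its use as a test of a cohort after. Single libraries stood apart in 36 of 580 groups of values tested (6.2%), by Dixon's ratio of the gap at one end of a group to its whole range. Chance alone gives about 1 in 20, or 29 here, and the ratios are given in parentheses. Wild-type control replicate 6, the only control of its group with a title number of 2000 or above, had 8 of them. Wild-type control replicate 6 was lowest for Afp (0.772), Cdkn1a (0.668), Cldn7 (0.861), Cyp2c40 (0.634), Cyp2c69 (0.805), Cyp3a41a (0.718), Cyp8b1 (0.696) and Nt5e (0.851). Wild-type tumour-bearing replicate 3 was highest for Loxl1 (0.782) and lowest for Abcb11 (0.696), Ces3b (0.671) and Cps1 (0.698). Mdr2-/- control replicate 1 was lowest for Cyp2c40 (0.629), Cyp2c69 (0.664), Sprr1a (0.815) and Sult3a2 (0.924). Mdr2-/- control replicate 6 was highest for Cyp3a16 (0.799), Cyp3a41a (0.689) and Igf2bp1 (1) and lowest for Efhd1 (0.804). Mdr2-/- control replicate 4 was highest for Cldn7 (0.717), Tgfb2 (0.677) and Timp1 (0.858). Wild-type tumour-bearing replicate 6 was highest for Gpc3 (0.625055) and Myo7b (0.778) and lowest for 7 abundant nuclear non-coding RNAs (0.763). Mdr2-/- tumour-bearing replicate 3 was highest for Afp (0.814), Igf2 (0.802) and Mcm5 (0.68). Mdr2-/- tumour-bearing replicate 1 was highest for Abcb4 (0.733) and lowest for Smpd3 (0.721). Mdr2-/- control replicate 3 was highest for Abcb1b (0.683) and C6 (0.828). Mdr2-/- tumour-bearing replicate 6 was highest for Prss35 (0.652). Mdr2-/- control replicate 5 was highest for Cyp4a14 (0.653). Wild-type control replicate 4 was lowest for Ang5 (0.683).

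The tumour effect differed between genotypes, by the edgeR interaction term, for 78 of 141 printed genes, against 4355 of 17216 genes tested. Many printed genes were chosen for large differences or effects. Values are log2 differences of the Mdr2-/- minus the wild-type effect. The effect was lower in Mdr2-/- by the largest amounts for Tinag (-4.84), Ang5 (-4.62), Gsta1 (-4.61), Sprr1a (-4.61), Slpi (-4.49), Cyp4a12a (-4.40), Smpd3 (-4.30), Trav4-1 (-4.22) and Gstm3 (-4.14). Next lowest were Mmp12 (-3.81), Ccl7 (-3.66), Mcm6 (-3.62), Ccl2 (-3.50), Hcar2 (-3.43), Cldn4 (-3.33), Ubd (-3.19), Ang4 (-3.12) and Mmp13 (-3.06). Smaller negative differences were those of Mcm5 (-3.00), Myo7b (-2.97), Ccl20 (-2.92), Col1a1 (-2.87), Sdcbp2 (-2.77), Cdkn1a (-2.57), Fam83a (-2.55), Timp1 (-2.47), Dnah1 (-2.37), Fosb (-2.29), Hp (-2.26), Cib3 (-2.24), Gpnmb (-2.22) and Itgax (-2.10). Below these in size came Ms4a7 (-1.99), Cidec (-1.92), C6 (-1.91), Wfdc2 (-1.65), Cygb (-1.63), Cyp2b13 (-1.61), Aurkb (-1.60), Cx3cr1 (-1.58), Adssl1 (-1.48), Pdgfrb (-1.16), Timd4 (-1.04), Hnf4a (-0.99), Asgr2 (-0.77), Dnase1l3 (-0.71) and Aqp1 (-0.48). The effect was higher in Mdr2-/- for Cyp3a44 (6.46), Cyp3a16 (6.28), Cyp3a41b (6.14), Cyp3a41a (5.95), Mup16 (5.51), Mup9 (5.44), Cyp2c69 (5.31), Mup7 (4.75), Mup19 (4.72), Cyp2c40 (4.47), Mup18 (4.45), Cdh16 (4.31) and Afp (4.30). Smaller positive differences were those of Hsd3b1 (3.57), Lrrn1 (3.36), Lrp2 (3.21), Sult3a1 (3.19), Sult3a2 (3.18), Efhd1 (2.53), Cyp7b1 (2.35), A1bg (2.08), Ces3b (2.02), Cyp4a14 (1.95), Acot1 (1.93), Malat1 (1.64), Slco1a1 (1.56), Lgr5 (1.55), Neat1 (1.5), Nt5e (1.23), Rgs5 (1.06) and Fabp1 (0.92). By camera, 13 lists differed, with these median differences: glycolysis (-0.40), cell cycle and DNA replication (-1.40), extracellular matrix and fibrosis (-1.06), Kupffer cell markers (-0.68), monocyte and infiltrating macrophage markers (-1.14), chemokines and myeloid growth factors (-1.43), sinusoidal endothelial cell markers (-0.45), MHC class I and antigen processing (-0.52), bacterial sensing and antimicrobial genes (-0.95), NRF2 and glutathione metabolism (-1.15), senescence and secretory phenotype (-0.57), female-biased liver genes (1.18) and abundant non-coding RNAs of rRNA-depletion libraries (1.29). None of them passed with an estimated correlation (adjusted p = 0.354 to 0.571, with 4 of 43 lists under an unadjusted p of 0.05 and 18 past fry).

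Leaving out 1 library moved 3 of these differences by more than 1.5 times. That of Afp came to 1.25 without Mdr2-/- tumour-bearing replicate 3, where its effect in Mdr2-/- was 0.84, and was still called. Those of Ccl20 and Ms4a7 lost their calls, at -1.85 without Mdr2-/- control replicate 4 and -1.17 without wild-type tumour-bearing replicate 3. The others stayed within 1.5 times, although calls were lost without these libraries (value then in parentheses). Among Mdr2-/- tumour-bearing libraries these were replicate 1 for A1bg (2.04) and Hnf4a (-0.90); replicate 2 for Aqp1 (-0.45) and Hnf4a (-0.99); replicate 5 for Fosb (-2.21); replicate 6 for Aqp1 (-0.43), Asgr2 (-0.65), Dnase1l3 (-0.59) and Hnf4a (-0.91). Among wild-type tumour-bearing libraries these were replicate 1 for Fosb (-2.19); replicate 3 for A1bg (2.00) and Ccl20 (-2.52); replicate 4 for Fosb (-2.19) and Hnf4a (-0.94); replicate 6 for A1bg (1.93), Asgr2 (-0.59), Fosb (-2.06) and Hnf4a (-0.76). Among Mdr2-/- control libraries these were replicate 1 for Hnf4a (-0.93); replicate 3 for Hnf4a (-0.99); replicate 4 for Ms4a7 (-1.70); replicate 6 for Hnf4a (-0.92). Among wild-type control libraries these were replicate 1 for Cdh16 (3.43) and Hnf4a (-0.99); replicate 2 for Fosb (-2.26); replicate 3 for Ccl20 (-2.77), Fosb (-2.26) and Hnf4a (-0.93); replicate 4 for Hnf4a (-0.98); replicate 5 for A1bg (1.85); replicate 6 for Ccl20 (-2.78), Fosb (-2.21), Hnf4a (-0.86) and Ms4a7 (-1.94). The call of Cyp2b13 was lost in 18 of 24 such fits (-1.68 to -1.43) and kept without Mdr2-/- tumour-bearing replicate 1, wild-type tumour-bearing replicates 3 and 5, Mdr2-/- control replicates 3 and 4 and wild-type control replicate 5.

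Other splits of the libraries into groups of the same sizes were refitted with edgeR, 100 per comparison with the real one included. For the tumour effect in Mdr2-/- mice the real split called 5995 genes, against at most 515 in the others, and in wild type 4891 genes, against at most 2037. For genotype in controls it called 8690 genes, against at most 4729, and in tumour-bearing livers 1917 genes, against at most 1756. Only the real split of 100 reached each count, narrowly in the last, which argues against chance but not a cohort. For the difference of the tumour effects, 3 of 100 splits called at least the real 4355, and the highest other called 6278. That share is under 0.05, but libraries of the 2 genotypes are not exchangeable here, since 8690 genes differed between the genotypes in controls. What the splits with more calls have in common was not tested.

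The share of 7 abundant nuclear non-coding RNAs separated Mdr2-/- tumour-bearing from Mdr2-/- control libraries completely. With the share as a covariate the log2 fold changes of the genes called for the tumour effect came to a median 0.452 of their size, where a ratio under 0.5 was set as the outcome if library composition were a cause, before this ratio but after the loss of calls was seen. The slope of the share comes from variation within groups, so the covariate also removes whatever biology varies with it, and how much of the tumour effect in Mdr2-/- mice is composition stays open. The title-number range as a covariate (5766 calls, 5995 without) argues against that split, but not finer cohorts, as the whole cause. The tumour itself remains an open explanation that this design does not separate from composition.

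Of the female-biased liver genes, 12 of 13 were lower in Mdr2-/- than in wild-type controls. The tables argue against male animals among the Mdr2-/- controls, where the summed CPM of 4 Y-linked genes reached at most 0.668. They argue against a general loss of hepatocyte transcripts, since the median of the list lay -2.83 from that of the hepatocyte list (-3.178 and -0.348). Reads shared within the Cyp2, Cyp3a and sulfotransferase families are not needed either, as 4 of 5 members outside those families were lower. A hypothesis is that the genotype, or the liver injury that comes with it, may lower this programme, a pattern found and tested on the same data. With the title-number range as a covariate the list passed camera at the preset correlation (adjusted p = 4.52e-07), and without the covariate it did not pass at an estimated one (adjusted p = 0.16 with an estimated correlation). A difference in age was not tested.

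Abcb1b, a neighbour of Abcb4 in GRCm38.p6, was higher in both Mdr2-/- groups. Reads shared with its near copy Abcb1a are argued against, because Abcb1a differed by 0.62 ± 0.27 in controls and Abcb1b by 4.27. A chromosome segment of another strain around the deleted gene cannot be told apart from an effect of the deletion. Of the 20 tested genes nearest to Abcb4, 2 (Abcb1b and Sema3e) were called the same way in both genotype comparisons besides Abcb4 itself, against a median of 1 and a 95th percentile of 4 over 15088 windows of that size, 37.8% of which held as many.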

How the results depend on the processing

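The fits without 1 library, without 2 libraries and with the non-coding RNA share as a covariate were chosen after the data were seen, and the other alternatives in advance. A sex term was not run, because the libraries did not fall into 2 clusters by Xist, and a class of rRNA genes was not analysed here. Among counts of genes, those that moved by more than 1.5 times are these. With the non-coding RNA share as a covariate the tumour effect in Mdr2-/- mice gave 960 genes and the difference of the tumour effects 2682. For genotype in tumour-bearing livers, total library size gave 2927 genes, limma voom with quality weights 4120, limma on log2(TPM + 1) 3306 and on log2(TPM + 0.1) 3069. Its range over fits without 1 library was 1116 to 2751. The corresponding ranges were 4122 to 6932 for the tumour effect in Mdr2-/-, 3521 to 5008 in wild type, 3457 to 5437 for their difference and 7712 to 9265 for genotype in controls. The causes of these shifts were not tested.

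Lists past camera numbered 11, 22, 13, 25 and 28 of 43 in the order tumour in Mdr2-/-, tumour in wild type, their difference, genotype in controls and genotype in tumour-bearing livers. With a correlation estimated per list camera passed 0 in each, with 1, 9, 4, 11 and 13 under an unadjusted p of 0.05, and fry passed 17, 30, 18, 33 and 27. With the non-coding RNA share as a covariate 19 lists passed in the first.

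Yap1 in Mdr2-/- tumours stood at -0.36 on log2(TPM + 1) by limma (adjusted p = 0.161), in wild-type tumours at 0.16 (adjusted p = 0.571), and between genotypes at 0.25 in tumour-bearing livers (adjusted p = 0.401), against -0.03 by edgeR (adjusted p = 0.944). Without the 2 libraries that stood apart the last was 0.18 by edgeR (adjusted p = 0.422). In controls it was 0.36 by edgeR (adjusted p = 0.0473) and 0.34 with DESeq2 size factors (adjusted p = 0.0581). Abcb4 was -0.45 in wild-type tumours without those 2 libraries (adjusted p = 0.0211, now past the threshold), and its difference of tumour effects was -0.003 on log2(TPM + 1) (limma adjusted p = 0.995). The causes were not tested. Genes called in both tumour comparisons with at least 2-fold change numbered 540 in the same and 102 in opposite directions, fewer because the threshold is stricter. As shares of summed TPM, which weights genes by length, the differences were -3.45 points for mitochondrial-encoded genes in wild-type tumours, -3.71 for the 10 most abundant genes there, -0.119 for those between tumour-bearing livers and 7.57 for the non-coding RNAs in Mdr2-/- tumours, none past the test. For the 10 most abundant genes in Mdr2-/- tumours the direction reversed, to 2.70 (exact permutation, adjusted p = 0.233).

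The printed genes are only some of those the naming rule gives, and they held more often than its full set. Of all 460 called results of the rule, 354 kept their call and direction under every alternative, 49 lost the call in at least 1 fit without a library, 106 under another setting, and 1 changed sign. Of 245 printed results, differences and uncalled ones included, 197 held and 0 calls changed sign. With the non-coding RNA share as a covariate, 17 printed calls were lost for the tumour effect in Mdr2-/-, with the fold change ± SE under it in parentheses. Those that shrank were Cyp1a2 (-0.56 ± 0.28), Dnase1l3 (-0.42 ± 0.17), Egr1 (-0.78 ± 0.63), Gpnmb (-1.02 ± 0.54, from -1.75 ± 0.39), Hnf4a (-0.26 ± 0.23), Lbp (-0.57 ± 0.18), Myo7b (-0.46 ± 0.26, from -1.71 ± 0.33) and Slco1a1 (0.22 ± 0.24). Those that kept most of their size, with larger SEs, were Abcb11 (-0.87 ± 0.29), Abcg5 (-0.62 ± 0.20), Ankrd1 (2.33 ± 0.78), Fosb (-1.73 ± 0.67), Igf2 (5.37 ± 1.58), Marco (-1.20 ± 0.47), Mcm6 (-1.09 ± 0.37), Slc7a11 (0.71 ± 0.34) and Tat (-0.82 ± 0.34). Afp and Igf2 lost theirs by limma voom and Igf2 on both TPM scales.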

Other observations

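The relations of Akt1 to marker scores were set out before their results were seen, and the comparison of the genotype effects was chosen after. The genotype effects in control and in tumour-bearing livers, which rest on separate libraries, shared 1129 called genes in the same direction. Of these, 756 were higher and 373 lower in Mdr2-/-, where independent lists would share 322 and 167, and 84 genes were called in opposite directions (34 higher and 50 lower in controls, against 181 and 298 for independent lists). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.418 and a Spearman rho of 0.322.

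Some lists that did not pass held called genes, in the same numbers adjusted over the list alone. Counts near the percent of all tested genes called (in parentheses) show no excess. For the tumour effect in Mdr2-/- (34.8%) these were mucin and intestinal or gastric epithelium genes (3 up of 9, camera adjusted p = 0.0562) and immune checkpoint and regulatory T cell genes (5 up of 11, camera adjusted p = 0.405). In wild type (28.4%) they were the mucin list (3 up and 1 down of 9, camera adjusted p = 0.239) and cholesterol synthesis genes (5 down of 18, camera adjusted p = 0.151). In Mdr2-/- against wild-type controls (50.5%) they were neutrophil markers (5 up of 10, camera adjusted p = 0.0559) and male-biased liver genes (4 up and 5 down of 12, camera adjusted p = 0.244).

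Akt1 differed between tumour-bearing livers of one group, and a hypothesis was that its level follows the bile duct marker score. In the 6 Mdr2-/- tumour-bearing libraries Pearson's r with the cholangiocyte score was 0.974 (exact permutation p = 0.0167, adjusted p = 0.0612 over 4 relations) and Spearman's rho 0.714 (exact permutation p = 0.136, adjusted p = 0.272). Without the 2 libraries farthest from the median r was 0.066, so the relation rests on those libraries. With the hepatocyte score r was -0.45 in Mdr2-/- (exact permutation, adjusted p = 0.525) and rho -0.543 (exact permutation p = 0.297, adjusted p = 0.396), with r at -0.535 without 2 libraries. In wild type r was -0.097 (exact permutation, adjusted p = 0.853) and rho -0.086 (exact permutation p = 0.919, adjusted p = 0.919), with r at -0.795 without 2 libraries. The cholangiocyte scores of wild-type libraries fell into clusters of 3 and 3, each too small for its own r, so no pooled r is given, although the relation counts among the 4 over which p was adjusted. For replicates 1 to 6, log2 CPM of Akt1 was 5.87, 6.02, 7.05, 6.09, 6.70 and 7.34, and the score, the mean of the markers relative to all libraries, -0.80, -0.52, 0.94, -0.80, 0.52 and 0.70.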
